A study of Mus musculus with 10 samples.

How the data were processed

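Bone marrow cells came from mice of the C57B/6 background with MLL-AF9-induced leukaemia. Per the labels, 100000 cells from leukaemic colonies that had been replated were injected into mice after 600 cGy of irradiation, and pIpC was given 2 to 3 weeks later to activate Cre. GFP marked the MLL-AF9 retrovirus and YFP the activity of Cre. Live leukaemic cells were sorted for GFP and YFP after exclusion of propidium iodide and gating on scatter. Total RNA was extracted with Trizol, amplified with a whole-transcriptome kit and labelled with biotin. The arrays held 3 WT, 4 Ezh2-null and 3 Eed-null samples.

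The intensity values in the value table had been made by the authors with RMA, per the submitters' processing notes in the labels, with the version not given in the sources used here. Their range showed a linear scale, with no value below 1, and the log2 was taken here after a floor of 1. A second deposited table held the intensities of the 7 WT and Ezh2-null arrays combined with another series and adjusted for batch with ComBat, per the file header. It was used only as an alternative for the Ezh2-null comparison with WT. It held 16 values below 0, which were set to the floor. Its 9 columns from the other series were not used here. Each of the 7 arrays was matched to its own column in the value table, with correlations of 0.993 to 0.995 against at most 0.984 for any other array.

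Control probe sets (64), probe sets with no symbol (5820), with several symbols (1399) or with a symbol turned into a date (56) were left out. The remaining 37762 probe sets had 1 symbol each. Of these, 31088 carried a symbol current in the reference table, 3656 were brought up to date through synonyms and 3018 were kept as given, among them symbols that the reference does not hold. Of the 20564 genes, 9541 had several probe sets, and the one with the highest mean over all arrays was kept. The reference table of the mouse assembly GRCm38.p6 was used for names and for the order of genes along chromosomes, and 18149 genes could be placed.

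The choices of test, lists and alternatives were made before the data were examined, apart from those named below. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit with 1 coefficient per genotype, eBayes with trend, two-sided), with all 10 arrays in 1 fit so that the groups share an estimate of the spread. The prior degrees of freedom were 3.48. P-values were adjusted by Benjamini-Hochberg over all genes of a comparison, and an adjusted p under 0.05 was called. They measure the spread between these samples. SE is the moderated standard error of limma and SD that of the arrays of a group. No overlap means that all values of one group lie above all values of the other.

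Genes were named by a fixed rule. In each comparison these were Ezh2, Eed, Suz12, Ezh1 and Cdkn2a whatever their result, the 8 largest rises and the 8 largest falls among called genes without overlap, and up to 4 members with the smallest p of each list described. Had fewer than 5 genes passed, the 10 with the smallest p would have been named. Members that pass adjusted over their list alone are named besides.

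The 23 fixed lists were PRC2 subunits, PRC1 subunits, the MLL-AF9 programme, Hox clusters B, C and D, developmental regulators bound by Polycomb, CDK inhibitors, imprinted genes, granulocyte genes, monocyte and macrophage genes, haematopoietic stem and progenitor genes, erythroid genes, megakaryocyte and platelet genes, B cell genes, T and NK cell genes, eosinophil, basophil and mast cell genes, stromal and endothelial genes, cell cycle genes, Myc and nucleolar genes, p53 target genes, interferon response genes, immediate early and stress genes, antigen presentation genes and sex-linked genes. They hold 484 different genes and were written from general knowledge. Each was tested with camera in limma with an inter-gene correlation preset at 0.01, two-sided, adjusted over the 23 lists of a comparison, and beside it with the correlation estimated and with the rotation test fry. Counts for fry use its directional p-values. Its mixed p-values, which take changes in either direction together, are given besides. Members were also adjusted over their list alone.

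Effects of the null groups were compared by the number of genes called in both per direction and by the correlation and covariance of log2 fold changes. Because both use the same WT arrays, 100 draws were simulated in which unchanged groups made from the residuals of the fit were set against the same WT arrays. After the result was seen, the same draws were also compared by the overlap of as many genes with the smallest p per direction as had been called, and by the genes that reached, in both comparisons, the lowest moderated t or log2 fold change of the shared genes.

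Alternatives tried were the ComBat table, the replicate number as a block, only the groups compared in the fit, the mean of all probe sets of a gene, each probe set separately, the lowest 40% of genes left out, quantile normalization, centring on the median, eBayes without trend, array weights, a threshold of 1 on the log2 fold change and leaving out each array. Chosen after the data were seen were leaving out WT replicate 3 and Eed-null replicate 1 together, leaving out the genes within 250 measured genes of Eed and the granulocyte score as a covariate. A score is the mean log2 intensity of a list on an array. Neighbourhoods were tested with Fisher's exact test, two-sided, adjusted over 15 tests, and the one around Eed again, unadjusted, with called genes at most 10 measured genes apart counted as 1 locus (the reference places H2-Q8 away from H2-Q7), relations between scores by permutation of deviations from group means, and splits of arrays by counting those that gave as many calls. Single arrays far from their group were sought with the Dixon ratio, whose critical value for 4 arrays is 0.829.

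The code was tested on simulated data with 20564 genes, in which 100 genes per comparison and size were given a log2 change of 1 or 2. It found 65% and 91% of them for Ezh2-null against WT, 57% and 90% for Eed-null against WT and 51% and 97% for Eed-null against Ezh2-null, with 12, 7 and 6 calls among unchanged genes. A planted shift of -0.5 in cell cycle genes was called in each comparison, with 0 other lists called. These results check the code only. They do not show how often camera calls an unchanged list whose members vary together, as members of some lists did here. The shares of genes found hold for many planted genes, which ease the adjusted threshold, whereas the data gave 5, 27 and 16 calls. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and NumPy 2.4.6, and plots were drawn with Matplotlib 3.10.9.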

Results

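RNA was profiled on expression arrays from primary mouse MLL-AF9 acute myeloid leukaemia, a disease made by putting the MLL-AF9 fusion gene into haematopoietic cells with a GFP-tagged retrovirus. Live bone marrow cells of leukaemic mice were sorted for GFP and for YFP, which marks cells in which Cre recombinase had been active. There were 3 WT, 4 Ezh2-null and 3 Eed-null arrays, which the submitters call biological replicates. Ezh2 is a catalytic subunit and Eed a core subunit of Polycomb repressive complex PRC2, a histone methyltransferase that keeps developmental genes silent. Probe sets were reduced to 1 per gene, and 20564 genes were tested. The median intensity lay between 137 and 144 on every array. Correlations across genes between arrays of one group were 0.959 to 0.978 in WT, 0.975 to 0.989 in Ezh2-null and 0.956 to 0.978 in Eed-null. The number of arrays limits the precision of every value. WT replicate 3 and Eed-null replicate 1 lay at the opposite ends of the first principal component, which held 28.6% of the variance, at -45.3 and 63.4.

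The targeted genes were read first in each array. The Ezh2 probe set read 10.25, 9.35 and 10.44 on the log2 scale in WT replicates 1, 2 and 3, and 9.19, 9.21, 9.36 and 8.91 in Ezh2-null replicates 1 to 4. The Eed-null arrays read 9.60, 9.71 and 9.49. The Ezh2 group means were 10.01 ± 0.58 (SD, n = 3) in WT and 9.17 ± 0.19 (SD, n = 4) in Ezh2-null, a log2 difference of -0.84 (SE 0.25) that did not pass (limma, adjusted p = 1.00). The Ezh2 value of WT replicate 2 lay within the Ezh2-null range, while its Bmi1, Hebp1 and Bmpr1a values lay with the other WT arrays. Eed read 10.52, 10.20 and 10.65 in WT, 10.79, 10.25, 10.40 and 10.30 in Ezh2-null, and 8.69, 8.34 and 8.67 in Eed-null. Eed therefore fell by 1.89 (SE 0.21) in Eed-null against WT (limma, adjusted p = 0.00797). A second, dimmer Eed probe set had group means of 5.94, 6.00 and 6.22 in WT, Ezh2-null and Eed-null. A probe set outside the deleted part of a gene checks nothing, and the position of these probe sets relative to the deleted exons is unknown here.

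The first comparison asked which genes differ between Ezh2-null and WT leukaemia. Donors and colonies behind each array are not known here, so differences between them cannot be told apart from genotype in any comparison. Bmi1, a subunit of the partner complex PRC1 with a known role in stem cell self-renewal, rose 3.88-fold, from 8.44 ± 0.25 (SD, n = 3) to 10.39 ± 0.19 (SD, n = 4) on the log2 scale. Hebp1, a haem-binding protein gene, rose 8.42-fold (log2 3.07, SE 0.30). Bmpr1a, which encodes a type I receptor for bone morphogenetic proteins, rose 6.76-fold (log2 2.76, SE 0.32), and Tcf24, a basic helix-loop-helix transcription factor gene, rose 6.55-fold (log2 2.71, SE 0.34). The non-coding transcript of the Rosa26 locus, Gt(ROSA)26Sor, fell by 2.07 (SE 0.25), from 6.72 ± 0.34 (SD, n = 3) to 4.66 ± 0.16 (SD, n = 4). The adjusted p-values (limma, two-sided) were 0.0101 for Bmi1 and Hebp1, 0.0327 for Bmpr1a and 0.0331 for Tcf24 and Gt(ROSA)26Sor. These 5 genes, 4 higher and 1 lower, were the only ones of 20564 to pass in this fit, and each separated the 2 groups with no overlap. Groups of 3 and 4 arrays separate by chance in 5.71% of genes, and 1029 of the 20564 genes separated. A second Bmi1 probe set differed by 1.99, whereas the probe sets of Bmpr1a ranged from 0.29 to 3.26. With 1 probe set per gene, Lrmda was not called. With each probe set tested separately, a dimmer Lrmda probe set at 2.79 passed (limma, adjusted p = 0.00261). The brighter one that was kept, at 1.57, did not pass there (limma, adjusted p = 0.0812). Suz12, another PRC2 core subunit, differed by -0.02 (SE 0.17), Ezh1, the alternative catalytic subunit, by -0.15 (SE 0.18), and the cell cycle inhibitor gene Cdkn2a by 0.57 (SE 0.34). None of these passed. Leaving out single arrays ended calls while the differences stayed of similar size. Where its call ended, Bmi1 was at 1.81 to 1.99, Hebp1 at 2.83 to 3.14, Bmpr1a at 2.56 to 2.92, Tcf24 at 2.46 to 2.90 and Gt(ROSA)26Sor at -2.22 to -1.88. Over all alternatives, Tcf24 ranged from 1.70 to 2.90 and kept its call in 5 of 22. Bmpr1a ranged from 1.63 to 2.98 and kept its call in 10 of 22. It lost the call with the mean of all probe sets and with quantile normalization. Without WT replicate 2 or Ezh2-null replicate 1, 3 or 4, limma called 0 genes, with 706, 672, 605 and 586 at an unadjusted p under 0.05 against 769 with all arrays. Without Ezh2-null replicate 2 it called 1 gene, without WT replicate 1 or 3 it called 2, and without Eed-null replicate 2 or 3, which enter through the shared spread, it called 3.

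**Figure D1:**
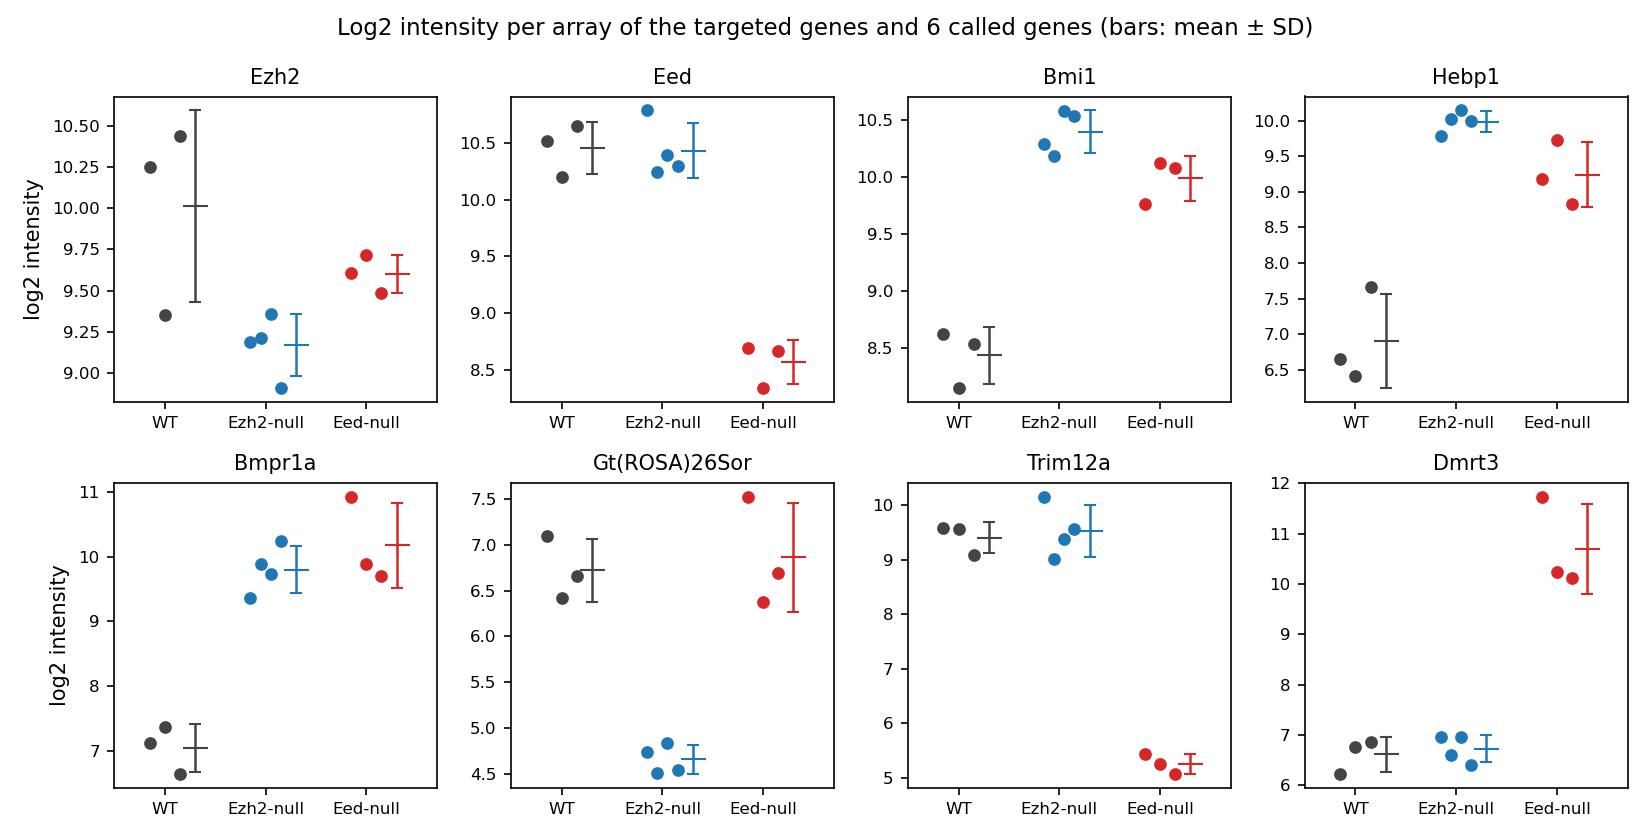
Log2 intensity (vertical axis) of Ezh2, Eed and 6 called genes in the 3 WT, 4 Ezh2-null and 3 Eed-null arrays, 1 point per array, with bars for the mean ± SD beside the points; each panel has its own axis range. Eed lies between 8.34 and 8.69 in Eed-null and at 10.20 or above in the other arrays, Bmi1, Hebp1 and Bmpr1a are higher in both null groups than in WT, and Gt(ROSA)26Sor is low in Ezh2-null.

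Among the gene lists, granulocyte genes, interferon response genes and immediate early genes shifted upward in Ezh2-null leukaemia relative to all other genes. Of 25 measured granulocyte genes, 22 had positive differences and the mean was 0.46 (camera, adjusted p = 1.98e-07; adjusted p = 0.741 with an estimated correlation). Trem1, a receptor that amplifies neutrophil activation, differed by 0.66 (SE 0.26), and the granule protein genes Ngp and Olfm4 by 0.57 (SE 0.27) and 0.85 (SE 0.34). None of the 25 passed over all genes or adjusted over the list alone. Of 21 interferon response genes, 17 were positive, with a mean of 0.29 (camera, adjusted p = 0.00204; adjusted p = 0.741 with an estimated correlation). Ifit3 and Ifit1, both antiviral genes, differed by 0.75 (SE 0.40) and 1.26 (SE 0.68). In that list 0 members passed over all genes or adjusted over the list alone (limma, with 0 at an unadjusted p under 0.05). Of 20 immediate early and stress genes, 14 were positive, with a mean of 0.17 (camera, adjusted p = 0.0475; adjusted p = 0.741 with an estimated correlation), among them the RNA decay factor gene Zfp36 at 0.56 (SE 0.22) and the nuclear receptor gene Nr4a1 at 1.02 (SE 0.48). Nr4a1 read 9.337, 7.107, 7.188 and 8.342 in Ezh2-null replicates 1 to 4, against 6.628 to 7.409 in WT. Again 0 members of the list passed either way in limma, with 2 at an unadjusted p under 0.05. Over all alternatives the adjusted p-values of these 3 lists ranged from 4.52e-10 to 0.918. Of 21 PRC1 subunits, Bmi1 passed over all genes, and Bmi1 and the corepressor gene Bcor (0.63, SE 0.15) passed adjusted over the list alone. The PRC1 list as a whole did not shift (camera in limma, adjusted p = 0.233). Of 18 B cell genes, the adaptor gene Bank1 (1.62, SE 0.31) passed adjusted over the list alone. WT replicate 3 had a mean granulocyte level of 10.98 against 12.16 and 12.08 in WT replicates 1 and 2, and a mean level of Myc and nucleolar genes of 10.71 against 9.68 and 9.38. Without WT replicate 3 the shifts were 0.09 for granulocyte, 0.17 for interferon and 0.07 for immediate early genes, and none of the 3 passed. Without Ezh2-null replicates 1, 2 or 4 the interferon shift was 0.20, 0.45 and 0.22 and passed only in the second case. The immediate early shift was -0.03 without Ezh2-null replicate 1, 0.06 without replicate 4, both no longer passing, and 0.47 without replicate 3. Leaving out Eed-null replicate 1 also ended the latter call at an unchanged 0.17. With the granulocyte score as a covariate the interferon mean was 0.076 and the immediate early mean -0.037, and neither passed. The immediate early call also ended with the replicate block (0.06), with only the groups compared (0.17), with the mean of all probe sets (0.16) and with quantile normalization (0.17).

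The comparison of Eed-null with WT leukaemia asked what differs where the core subunit, which PRC2 needs with either catalytic subunit, is lost. Dmrt3, a developmental transcription factor gene, rose 17.1-fold, from 6.61 ± 0.34 to 10.70 ± 0.90 (SD, n = 3 each). Its WT and Ezh2-null values (6.22 to 6.96) lay below the array medians of all genes (7.42 to 7.49), so its fold changes rest on a dim baseline. H2-Q7 and H2-Q8, non-classical class I histocompatibility genes, rose by log2 3.90 (SE 0.50) and 3.45 (SE 0.46). Ctse, the aspartic protease cathepsin E, rose 11.2-fold (log2 3.49, SE 0.51). Bmpr1a rose 8.76-fold (log2 3.13, SE 0.34), Rspo1, a secreted enhancer of Wnt signalling, 6.77-fold (log2 2.76, SE 0.27), and Bmi1 2.93-fold (log2 1.55, SE 0.20). Trim12a, an antiviral restriction factor gene of the Trim5 group, fell by 4.15 (SE 0.27), from 9.41 ± 0.28 to 5.25 ± 0.18 (SD, n = 3 each), and its family members Trim30d and Trim5 fell by 2.76 (SE 0.35) and 1.70 (SE 0.20). Penk, the precursor of enkephalin peptides, fell by 2.37 (SE 0.29). The adjusted p-values (limma, two-sided) of the genes named so far in this comparison lay between 0.000364 for Trim12a and 0.0341 for Ctse. In all, 27 genes passed, 18 higher and 9 lower, and all 27 separated the groups with no overlap, which chance gives in 10% of genes for 3 against 3 and which 12.8% of all genes showed. The secreted protein gene Retnla (log2 2.95, SE 0.44) and Armcx2 (log2 2.84, SE 0.39) were also among the largest rises, and C030014L02 (-1.80, SE 0.22), the peptide hormone gene Insl5 (-1.38, SE 0.21) and Gtsf1l (-1.14, SE 0.17) among the largest falls. H2-Q and Trim genes belong to families whose probe sets can share sequence, so which member a value belongs to is uncertain. The probe sets of Dmrt3 ranged from 0.08 to 4.09, those of Bmpr1a from 0.37 to 3.76 and those of Armcx2 from 0.28 to 2.84. Ezh2 differed by -0.41 (SE 0.27), Suz12 by -0.18 (SE 0.18), Ezh1 by 0.11 (SE 0.20) and Cdkn2a by 0.63 (SE 0.37), and none of these passed. With only the WT and Eed-null arrays in the fit, 1 gene, Trim12a, passed. The count was 14 without WT replicate 1, 15 without WT replicate 2, 14 without Ezh2-null replicate 3, 12 without Ezh2-null replicate 4 and 42 without Eed-null replicate 2. Of the genes with the largest changes, 5 of 16 (Dmrt3, Bmpr1a, Rspo1, Trim12a and Eed) passed whichever array was left out, while each single array ended between 2 and 9 of the other calls. Differences stayed of similar size where calls ended, such as 3.05 to 3.78 for Ctse and 2.42 to 2.95 for Armcx2.

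Several lists shifted in Eed-null leukaemia against WT. Cell cycle genes were lower: all 30 had negative differences, with a mean of -0.51 (camera, adjusted p = 7.39e-10; adjusted p = 0.490 with an estimated correlation). The mitotic motor Kif11 (-1.26, SE 0.28), cyclin A2 (Ccna2, -1.32, SE 0.31), topoisomerase Top2a (-1.15, SE 0.27) and the spindle factor Tpx2 (-1.13, SE 0.32) passed adjusted over the list alone, and 0 passed over all genes (limma, 11 at an unadjusted p under 0.05). Of 24 Myc and nucleolar genes, 21 were negative, with a mean of -0.37 (camera, adjusted p = 0.00152; adjusted p = 0.529 with an estimated correlation). The ribosome biogenesis genes Polr1b and Bop1 differed by -0.73 (SE 0.22) and -0.65 (SE 0.20), with 0 members passing either way in limma and 3 at an unadjusted p under 0.05. Monocyte and macrophage genes had a mean of -0.56 (camera, adjusted p = 0.00679; adjusted p = 0.490 with an estimated correlation). Of the 26, the chemokine receptor genes Ccr2 (-3.03, SE 0.74) and Cx3cr1 (-1.69, SE 0.47) and the macrophage glycoprotein gene Cd68 (-1.24, SE 0.31) passed adjusted over the list alone and 0 over all genes, with 5 at an unadjusted p under 0.05. Ccr2 read 5.608 in Eed-null replicate 1 but 9.036 and 8.624 in replicates 2 and 3, against 9.961 to 11.232 in WT. Granulocyte genes had a mean of 0.42, with 21 of 25 positive (camera, adjusted p = 0.00564; adjusted p = 0.490 with an estimated correlation). Interferon response genes had a mean of 0.45, with 16 of 21 positive (camera, adjusted p = 0.00679; adjusted p = 0.490 with an estimated correlation), including Oasl2 at 1.77 (SE 0.66) and Rtp4 at 1.24 (SE 0.41). In both lists 0 members passed over all genes or adjusted over the list alone, with 2 and 7 at an unadjusted p under 0.05.

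Hox genes of clusters B, C and D, which Polycomb complexes keep silent in many tissues, had a mean difference of 0.21 in Eed-null against WT, with 20 of 25 positive (camera, adjusted p = 0.00679; adjusted p = 0.490 with an estimated correlation). Hoxc4 differed by 0.86 (SE 0.30) and Hoxc10 by 0.41 (SE 0.10). Hoxc4 read 6.755 in Eed-null replicate 2 but 5.356 and 5.602 in replicates 1 and 3, against 4.843 to 5.22 in WT. Of the list, 0 passed either way, with 5 at an unadjusted p under 0.05 in limma. Of 48 developmental regulators bound by Polycomb, 36 were positive, with a mean of 0.14 (camera, adjusted p = 0.0224; adjusted p = 0.556 with an estimated correlation), and the LIM homeobox gene Lhx2 (1.10, SE 0.22) passed adjusted over the list alone. The PRC2 subunits had a mean of -0.28 (camera, adjusted p = 0.0119; adjusted p = 0.490 with an estimated correlation), in which the targeted gene Eed was the 1 of 12 members to pass, over all genes and adjusted over the list alone. The list call rested on Eed and ended with the genes near Eed, Eed among them, left out. Over all alternatives the adjusted p-values of the 8 shifted lists ranged from 2.63e-14 to 0.931. Antigen presentation genes did not shift as a list (camera in limma, adjusted p = 0.817), while H2-K1 (1.10, SE 0.26), B2m (0.49, SE 0.15) and Psmb9 (0.67, SE 0.21) of the class I pathway were higher and H2-DMa (-1.12, SE 0.37) of the class II pathway lower, all adjusted over the list alone. H2-DMa read 7.475 in Eed-null replicate 1 but 9.128 and 8.87 in replicates 2 and 3, against 9.384 to 9.962 in WT. The p53 target gene Zmat3 (0.84, SE 0.21) also passed adjusted over its list alone. Without WT replicate 3, the array low in granulocyte genes and high in Myc and nucleolar genes, the means became 0.04 for granulocyte, 0.02 for Myc and nucleolar, 0.33 for interferon, -0.23 for PRC2 and 0.13 for developmental genes. These 5 calls ended. Calls also ended without WT replicate 1 for Hox (0.17), developmental (0.09) and monocyte genes (-0.46), without WT replicate 2 for monocyte (-0.41) and interferon genes (0.43), without Eed-null replicate 1 for developmental genes (0.11) and without Eed-null replicate 3 for PRC2 subunits (-0.25). At the preset correlation of 0.01, the cell cycle shift passed whichever array was left out but was -0.31 without Eed-null replicate 3. The Myc and nucleolar mean was -0.64 without WT replicate 2 and -0.22 without Eed-null replicate 1. The estimated correlation was 0.613 for cell cycle and 0.645 for Myc and nucleolar genes. The preset thus treats their members as nearly independent, and passing at it does not show a shift beyond the spread between arrays. With the granulocyte score as a covariate the calls of interferon (0.26), Myc and nucleolar (0.078), PRC2 (-0.23) and developmental genes (0.14) ended, besides the granulocyte call, which ends by construction. The Hox and developmental scores were 6.01 to 6.34 and 5.74 to 6.06, below the array medians of all genes (7.42 to 7.49), so both lists were dim on average. Some uncalled lists had means of similar size, with megakaryocyte and platelet genes at 0.25, T and NK cell genes at 0.20 and B cell genes at 0.14. Others were nearer 0, with erythroid genes at 0.07, stromal and endothelial genes at 0.06 and sex-linked genes at 0.01. With the lowest 40% of genes left out, the calls of Hox (0.23), developmental (0.24) and PRC2 genes (-0.28) ended. Quantile normalization ended that of developmental genes (0.10), and leaving out WT replicate 3 and Eed-null replicate 1 together also that of Hox genes (0.18).

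**Figure D2:**
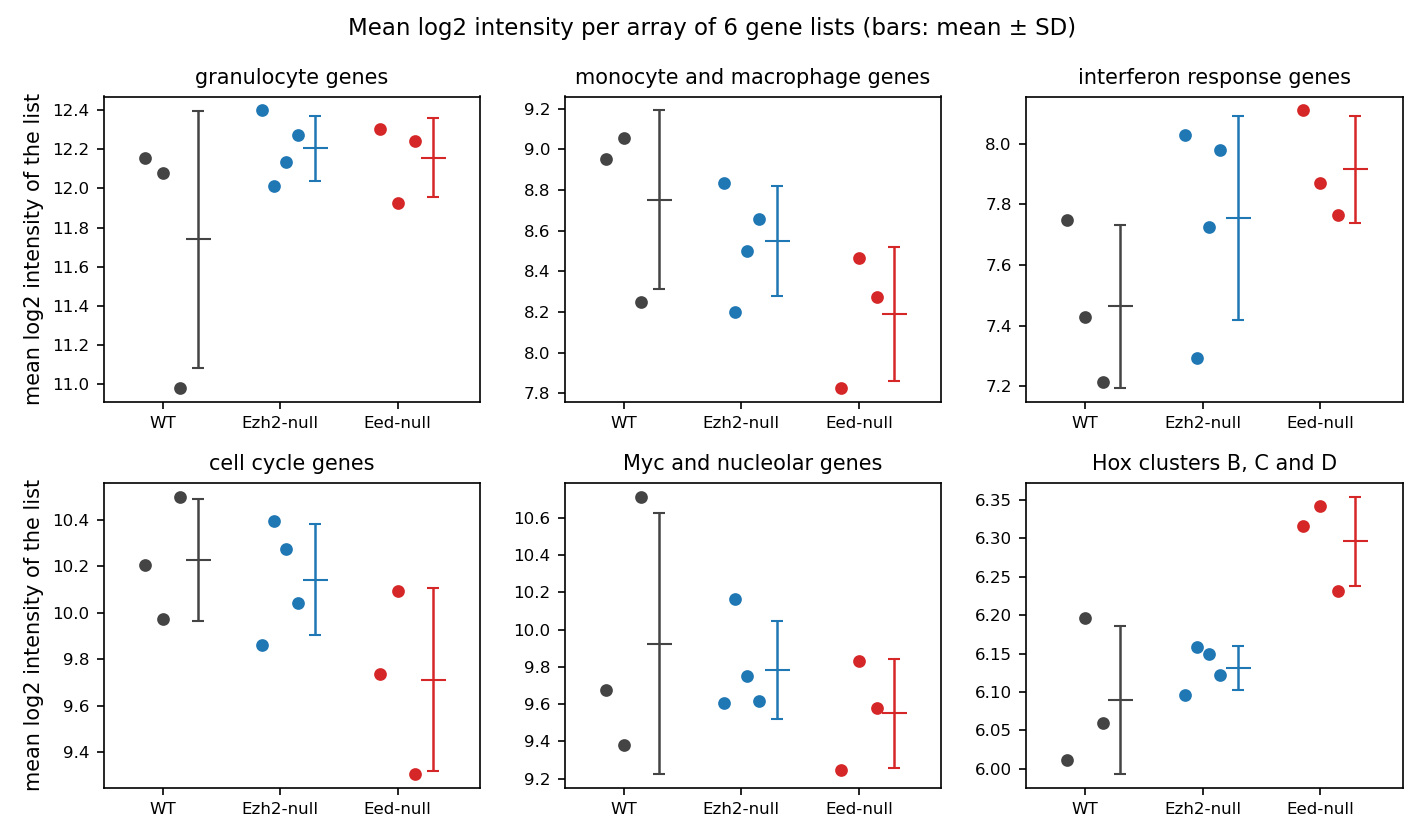
Mean log2 intensity (vertical axis) of 6 gene lists in the 3 WT, 4 Ezh2-null and 3 Eed-null arrays, 1 point per array, with bars for the mean ± SD beside the points; each panel has its own axis range. WT replicate 3 is the low point for granulocyte genes (10.98) and the high point for Myc and nucleolar genes (10.71), and the 3 Eed-null arrays lie above the other arrays for Hox genes of clusters B, C and D.

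The direct comparison of Eed-null with Ezh2-null leukaemia asked where the effects of losing the core subunit and a catalytic subunit differ, and equals the difference between their effects against the same WT arrays. Dmrt3 was 15.7-fold higher in Eed-null (log2 3.97, SE 0.36), from 6.73 ± 0.28 (SD, n = 4) in Ezh2-null to 10.70 ± 0.90 (SD, n = 3). Ctse was higher by 3.55 (SE 0.47), the class I histocompatibility gene H2-Q10 by 2.67 (SE 0.28), the lipid transfer gene Stard10 by 2.55 (SE 0.26), Rspo1 by 2.49 (SE 0.25). Npl, an enzyme of sialic acid breakdown, was higher by 1.87 (SE 0.19). Trim12a fell by 4.27 (SE 0.26), Trim30d by a log2 difference of -3.18 (SE 0.33), Penk by -2.78 (SE 0.27), Trim5 by -1.88 (SE 0.19) and Eed by -1.86 (SE 0.19). The cadherin family gene Pcdh7 (2.26, SE 0.31) and Gt(ROSA)26Sor (2.21, SE 0.25) were higher in Eed-null, and Lrmda (-1.73, SE 0.22) was lower. Against WT, Gt(ROSA)26Sor differed by 0.14 in Eed-null and -2.07 in Ezh2-null, and Lrmda by -0.16 and 1.57, so for both it was Ezh2-null that lay apart. H2-Q10 differed from WT by 1.83 and -0.84 and Pcdh7 by 1.85 and -0.41 in these groups, and neither was called against WT. A dimmer Lrmda probe set differed by -2.92 between Eed-null and Ezh2-null and by 2.79 between Ezh2-null and WT. Both differences passed with each probe set tested separately (limma, adjusted p = 0.00081 and 0.00261). In limma, 16 genes passed, 10 higher and 6 lower in Eed-null, with adjusted p-values from 0.000138 to 0.0243, and all separated the groups with no overlap, which 10.5% of all genes did against 5.71% by chance. Bmi1, Hebp1 and Bmpr1a did not pass, with adjusted p-values of 0.548, 0.516 and 0.737. Ezh2 differed by 0.43 (SE 0.25), Suz12 by -0.16 (SE 0.17), Ezh1 by 0.26 (SE 0.18) and Cdkn2a by 0.06 (SE 0.34), none of which passed. Without Eed-null replicate 1 the count was 36 and without Eed-null replicate 3 it was 28. Of the 14 genes with the largest changes, Ctse, Pcdh7 and Lrmda were the ones whose calls ended on leaving out a single array. For Pcdh7 this was WT replicate 2 or any Ezh2-null array (limma, adjusted p up to 0.115), for Ctse WT replicate 1, Ezh2-null replicate 3 or Eed-null replicate 2 or 3 (up to 0.102), and for Lrmda Ezh2-null replicate 3 or Eed-null replicate 2 (up to 0.0569).

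Of the lists, cell cycle genes were lower in Eed-null than in Ezh2-null, with 28 of 30 negative and a mean of -0.43 (camera, adjusted p = 2.29e-10; adjusted p = 0.907 with an estimated correlation). Ccna2 (-1.25, SE 0.29) passed adjusted over the list alone and 0 passed over all genes in limma, with 10 at an unadjusted p under 0.05. Developmental regulators bound by Polycomb were higher, with 40 of 48 positive and a mean of 0.15 (camera, adjusted p = 0.00549; adjusted p = 0.907 with an estimated correlation), and Lhx2 (1.34, SE 0.21) passed adjusted over the list alone. Hox genes of clusters B, C and D had a mean of 0.16, with 18 of 25 positive (camera, adjusted p = 0.0266; adjusted p = 0.907 with an estimated correlation), such as Hoxc4 at 0.84 (SE 0.28), which was highest in Eed-null replicate 2 (6.755). Monocyte and macrophage genes had a mean of -0.36 (camera, adjusted p = 0.0277) and Myc and nucleolar genes of -0.23 (camera, adjusted p = 0.00964), both with an adjusted p = 0.907 with an estimated correlation, with Cx3cr1 at -1.45 (SE 0.44) and Bop1 at -0.54 (SE 0.18). None of the members of these last 3 lists passed over all genes or adjusted over the list alone. The platelet adhesion gene Selp (2.01, SE 0.39) and H2-K1 (0.94, SE 0.24) passed adjusted over their lists alone, and their lists did not shift (camera in limma, adjusted p = 0.103 and 0.685). Over all alternatives the adjusted p-values of the 5 shifted lists ranged from 2.57e-15 to 0.907. Without Eed-null replicate 1 the Hox (0.15), developmental (0.11), monocyte (-0.18) and Myc and nucleolar (-0.08) calls ended. So did the Hox call without Eed-null replicate 2 (0.14), the monocyte call without Ezh2-null replicate 1 (-0.26) or 4 (-0.32) and the Myc and nucleolar call without Ezh2-null replicate 2 (-0.11). The Myc and nucleolar mean was -0.37 without Eed-null replicate 2. The cell cycle mean, which passed at the preset correlation whichever array was left out, was -0.23 without Eed-null replicate 3. The Hox and developmental lists were dim on average. Of the uncalled lists, megakaryocyte and platelet genes gave 0.26 and eosinophil, basophil and mast cell genes 0.21, both above the Hox and developmental means. Stromal and endothelial genes gave 0.13 and sex-linked genes 0.10, while T and NK cell genes gave 0.05, B cell genes 0.03 and erythroid genes 0.01. With the lowest 40% of genes left out and with quantile normalization, only the cell cycle call stayed, with Hox genes at 0.13 and 0.12, developmental genes at 0.11 and 0.09, monocyte genes at -0.50 and -0.36 and Myc and nucleolar genes at -0.23 and -0.21. The replicate block ended the Hox (0.16) and monocyte (-0.32) calls, and the granulocyte covariate the monocyte call (-0.33).

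Bmi1, Hebp1 and Bmpr1a were the 3 genes higher than WT in both null groups, and 0 genes were lower in both or opposite in direction (limma, adjusted p under 0.05 in each comparison). Independent lists of these sizes would share 0.00350 genes higher and 0.000438 lower, but the WT arrays are shared. In 100 simulated draws of unchanged groups against shared simulated WT arrays, 0 genes were called higher in both in every draw. Any genes were called in 2 draws for Ezh2-null (up to 2059) and 3 for Eed-null (up to 1094), never in the same draw, so that a shared call could not arise. By rank, a comparison added after this was seen, 3 or more of the 4 and 18 higher genes with the smallest p were shared in 14 of 100 draws (mean 0.87, at most 4), but ranks take no account of the size of the changes. By moderated t, also added later, the 3 genes reached at least 7.17 in both comparisons, and in 100 draws 0 genes did. By log2 fold change alone, 12 genes reached 1.55 in both, and 6 of 100 draws gave as many. Shared WT arrays alone gave changes as large in these draws. The t limit was taken from the 3 genes themselves, and no draw had calls in both comparisons. Its count of 0 therefore adds little and does not set the shared controls aside. Across all genes, which are not independent replicates, the 2 effects correlated at r = 0.537, against a simulated mean of 0.474 (SD 0.357) from the shared WT arrays alone, and 51 of the 100 draws were as high. Their covariance was 0.0550 against a simulated 0.0346, a difference of 0.0204 that 26 of 100 draws reached or passed. The 3 WT arrays cannot be split into sets of 2, so part of any excess may come from the shared controls. Tcf24 had a mean of 8.46 ± 0.35 (SD, n = 3) in Eed-null against 6.96 ± 0.44 (SD, n = 3) in WT, which did not pass. The difference between its 2 effects did not pass either (limma, adjusted p = 0.343). The number of shared genes was 0 without WT replicate 2 or Ezh2-null replicate 1, 3 or 4, and 1 without WT replicate 1, Ezh2-null replicate 2 or Eed-null replicate 2, while 2 remained without WT replicate 3 or Eed-null replicate 1 or 3.

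**Figure D3:**
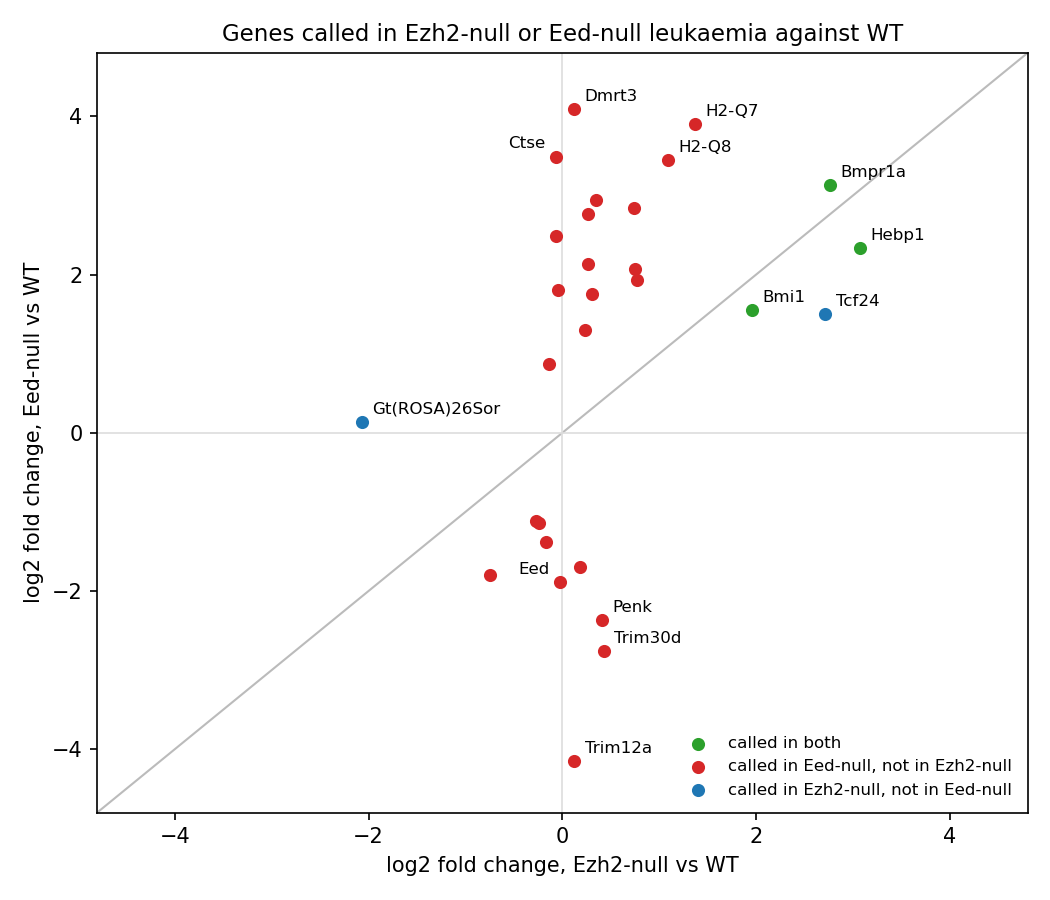
Log2 fold change against WT in Ezh2-null (horizontal axis) and in Eed-null (vertical axis), 1 point per gene called in either comparison, with the line of equal effects. Bmi1, Hebp1 and Bmpr1a were called in both, Gt(ROSA)26Sor and Tcf24 only in Ezh2-null, and Dmrt3, Ctse and Trim12a, called in Eed-null, lie at 0.12, -0.06 and 0.12 on the Ezh2-null axis.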

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

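The tests on the genes near Eed, on the granulocyte genes and on the cell cycle genes were chosen only after these results were seen, and the counts over other splits of the arrays were planned.

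Of the genes called in Eed-null against WT, 4 lie near Eed on its chromosome: Stard10, Trim5, Trim12a and Trim30d, at 80, 121, 122 and 126 measured genes from it, and all 4 also differed from Ezh2-null whichever array was left out (against WT, the calls of Trim5 at -1.72 and Trim30d at -2.45 ended without WT replicate 1, and that of Trim30d at -2.79 without Eed-null replicate 3). Loss of a PRC2 function shared by both null groups is argued against by the Ezh2-null effects of these genes, which had a median of -0.15 when counted positive in the direction of the Eed-null change (-0.07, 0.18, 0.12 and 0.43, with SE of 0.26, 0.19, 0.26 and 0.33). Probes that match the Eed-null allele less well are argued against for Stard10, which was higher by 2.49, whereas for the 3 Trim genes this cannot be told apart from lower expression, since the second Trim30d probe set also differed by -2.17, and no probe sequences were used here. Sequence flanking the engineered Eed allele and carried along with it cannot be told apart from an effect of Eed loss either: 4 of 500 genes within 250 measured genes of Eed were called against WT and 20 of 17647 elsewhere (Fisher's exact test, two-sided, adjusted p = 0.0293, and 0.00915 against Ezh2-null), but the window was chosen after the genes were seen, and with the 3 neighbouring Trim genes counted as 1 locus, 2 loci of 498 against 20 of 17647 gave p = 0.121 (Fisher's exact test, unadjusted, and 0.0480 against Ezh2-null). The strain in which the allele was made is not given in the sources used here, and an effect of Eed loss on these genes that Ezh2 loss does not have also stays open.

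Granulocyte genes were higher in both null groups than in WT, by a mean of 0.46 in Ezh2-null and 0.42 in Eed-null. Without WT replicate 3 the means were 0.086 and 0.039 and neither passed, so a single WT array low in granulocyte genes may account for most of both shifts. On that array the late granule genes Ltf and Lcn2 read 10.05 and 10.69 against 13.62 and 13.24 in WT replicate 1, while of the early granule genes Elane, Ctsg and Prtn3 read 12.31, 12.98 and 11.52 against 12.30, 12.51 and 11.24, but Mpo 12.58 against 13.32. Different shares of mature cells in the sorted samples could produce such a pattern, and among arrays of one group the granulocyte score went against the Myc and nucleolar score (r = -0.939, permutation p = 0.00019, 10 arrays, -0.935 without WT replicates 1 and 3). The leukaemia is itself myeloid and the sort for GFP and YFP would remove normal myeloid cells that lack the retrovirus, so a larger share of mature leukaemic cells stays open.

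Cell cycle genes were lower in Eed-null than in WT, by a mean score of -0.51 with an SE between arrays of 0.24. Without Eed-null replicate 3 the shift was -0.31 (SE 0.23), the nearest to 0 for any array left out, and with the granulocyte score as a covariate it was -0.29 (SE 0.22). Neither 1 array nor a different share of mature cells can be told apart from an effect of Eed loss here, because what is left of the shift lies within 2 SE of 0 and yet is more than the part removed. A slower division of Eed-null leukaemia cells may, but need not, be part of the pattern. Cdkn2a, a candidate for such an effect, differed by 0.63 (SE 0.37) and did not pass in limma.

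How often other splits of the same arrays give as many calls was counted. Of the 35 splits of the WT and Ezh2-null arrays, 1, the real one, gave 5 genes, and the highest other count was 0. For this count chance is argued against only at a share under 0.05, since 1 of 35 is the smallest share these arrays allow. Of 100 simulated draws of unchanged groups, 2 gave as many calls (up to 2059). Without WT replicate 2 or Ezh2-null replicate 1, 3 or 4, limma called 0 genes. Of all genes, 3.74% had an unadjusted p under 0.05 in limma, fewer than that threshold gives by chance. The groups separated with no overlap in 1029 of 20564 genes, against 5.71% by chance. By these 2 shares, Ezh2-null against WT showed no excess over the chance averages. Genes vary together, so the shares can lie far from those averages by chance, and they do not show that an effect is absent. On leaving out an array, 586 (without Ezh2-null replicate 4) to 1288 genes (without WT replicate 1) had an unadjusted p under 0.05 in limma, against 769 with all arrays. For Eed-null against Ezh2-null, 1 of 35 splits, the real one, gave 16 genes and the highest other count was 0. For Eed-null against WT the 10 splits are too few for a share under 0.05, with 27 genes in the real one and at most 0 in the others, which leaves 1 of 10.

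Among 52 groups of 4 Ezh2-null values searched for a single distant array, 2 passed the Dixon limit, while chance alone would give 2.6. Insl5 was low in Ezh2-null replicate 2 (6.28, ratio 0.851). The erythroid score was low in Ezh2-null replicate 1 (6.56, ratio 0.835).

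The effects of Eed loss and Ezh2 loss against the same WT arrays differed in 16 genes (limma, adjusted p under 0.05). Those named by the rule were higher in Eed-null for Dmrt3 (3.97), Ctse (3.55), H2-Q10 (2.67), Stard10 (2.55), Rspo1 (2.49), Pcdh7 (2.26), Gt(ROSA)26Sor (2.21) and Npl (1.87), and lower for Trim12a (-4.27), Trim30d (-3.18), Penk (-2.78), Trim5 (-1.88), Eed (-1.86) and Lrmda (-1.73). For Gt(ROSA)26Sor and Lrmda, Eed-null lay near WT (0.14 and -0.16) and Ezh2-null lay apart (-2.07 and 1.57). The lists whose effects differed by camera were Hox clusters B, C and D (0.16), developmental regulators bound by Polycomb (0.15), monocyte and macrophage genes (-0.36), cell cycle genes (-0.43) and Myc and nucleolar genes (-0.23), none of which passed with an estimated correlation.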

How the results depend on the processing

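Leaving out WT replicate 3 and Eed-null replicate 1 together, leaving out genes near Eed and the granulocyte covariate were chosen after the data were seen, and the other alternatives were planned. Of 35 named gene calls, 35 kept their sign under every alternative run, 5 also kept their call under all of them (Trim12a in both Eed-null comparisons, and Gt(ROSA)26Sor, Trim30d and Penk in Eed-null against Ezh2-null) and 16 kept it whichever array was left out. Of 16 list calls, 13 kept their sign, 0 kept their call under all alternatives (none passed in camera with an estimated correlation) and 2, the cell cycle calls, kept it whichever array was left out. Over the alternatives of the genes named among the largest changes or whatever their result, and of the 16 called lists, 816 and 270 values stayed on the same side of the threshold, 167 and 77 no longer passed and 19 and 6 changed sign. Unless stated, the cause of a moved count or a changed sign was not tested.

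For Ezh2-null against WT, limma called 5 genes. It called 10 with each probe set separately, 2 with quantile normalization, 3 without trend and 2 with the granulocyte covariate, and from 0 (without WT replicate 2) to 4 (without Eed-null replicate 1) on leaving out an array. With the ComBat table it called 5, of which Gt(ROSA)26Sor, Bmpr1a, Hebp1 and Bmi1 were the same, Tcf24 was lost and Lpl (-2.01) gained. The ComBat table holds no Eed-null arrays, and Tcf24 was also lost with only the groups compared, so its loss cannot be credited to ComBat. Of 3 lists, 0 were called with an estimated correlation and 0 with fry, and from 1 (without Ezh2-null replicate 4) to 8 (without WT replicate 2) on leaving out an array. In the mixed form of fry the PRC1 list, which holds the called gene Bmi1, passed (adjusted p = 3.43e-08). With the granulocyte covariate 3 were called, of which 0 were among the first 3. Immediate early and stress genes turned to -0.037 with the granulocyte covariate and ranged from -0.025 (without Ezh2-null replicate 1) to 0.47 (without Ezh2-null replicate 3). Values near 0 that did not pass also changed sign. Eed (-0.03) was 0.020 with the mean of probe sets, 0.0035 with quantile normalization and 0.071 without WT replicate 3 and Eed-null replicate 1, with a range of -0.15 (without WT replicate 2) to 0.071 (without WT replicate 3). Suz12 (-0.02) was 0.038 with the mean of probe sets, 0.14 without both arrays and 0.12 with the granulocyte covariate, with a range of -0.13 (without WT replicate 2) to 0.14 (without WT replicate 3).

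For Eed-null against WT, limma called 27 genes. It called 1 with only the groups compared, 43 with each probe set separately and from 12 (without Ezh2-null replicate 4) to 42 (without Eed-null replicate 2) on leaving out an array. Of 8 lists, 0 were called with an estimated correlation, 0 with fry, 8 with the lowest 40% left out (5 the same), 3 without both arrays, 4 with the granulocyte covariate and from 4 (without WT replicate 3) to 9 (without Ezh2-null replicate 2) on leaving out an array. In the mixed form of fry, PRC2 and PRC1 subunits passed (adjusted p = 9.58e-06 each), which hold the called genes Eed and Bmi1. So did antigen presentation genes (0.00915), Hox clusters B, C and D (0.0124) and megakaryocyte and platelet genes (0.0124). Granulocyte genes turned to -0.033 without both arrays. Myc and nucleolar genes turned to 0.18 without both arrays and 0.078 with the granulocyte covariate, and ranged from -0.64 (without WT replicate 2) to 0.022 (without WT replicate 3). With genes near Eed left out, which by construction removes Eed, Stard10, Trim5, Trim12a and Trim30d, 20 genes were called, and the call of the PRC2 list, which had rested on Eed, ended.

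For Eed-null against Ezh2-null, limma called 16 genes. It called 28 with the mean of probe sets, 25 with each probe set separately, 50 with array weights, 44 without both arrays, 25 with the granulocyte covariate and from 13 (without Ezh2-null replicate 3) to 36 (without Eed-null replicate 1) on leaving out an array. Of 5 lists, 0 were called with an estimated correlation, 0 with fry, 1 with the lowest 40% left out, 1 with quantile normalization, 1 without both arrays and from 1 (without Eed-null replicate 1) to 5 (without WT replicate 1) on leaving out an array. Cdkn2a (0.06) was -0.11 with array weights and ranged from -0.23 (without Eed-null replicate 2) to 0.37 (without Ezh2-null replicate 3). On leaving out a single array, the 3 genes called in both comparisons with WT became from 0 (without WT replicate 2) to 2 (without WT replicate 3). With the mean of all probe sets they became 4.

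The groups share replicate numbers, and nothing in the labels says that these pair animals. Deviations of arrays with the same number correlated at -0.233 to 0.361, and not every array correlated best with its own number. For Ezh2-null with Eed-null each same-number value (0.0335, 0.170 and 0.0376) was above the others, for WT with either group it was not. The numbers were therefore not used as pairs, though a link between some of them is not excluded. With the replicate block limma called 0 genes in Ezh2-null against WT (655 at an unadjusted p under 0.05), 16 in Eed-null against WT and 4 in Eed-null against Ezh2-null, 0 in both comparisons with WT and 3 lists in Eed-null against Ezh2-null. Eed and Suz12 were 0.019 and 0.047 in Ezh2-null against WT and Cdkn2a -0.0045 in Eed-null against Ezh2-null. Number 4 occurs in 1 group, so the block takes Ezh2-null replicate 4 out of the comparisons.

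A batch block and the ComBat table for the overlap were not run, since the sources used here do not name the batches given to ComBat and the table holds no Eed-null arrays. Under its own covariate the granulocyte list is 0 by construction.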

Other observations

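The remaining lists are given as means of log2 fold changes with adjusted p from camera in limma, for Ezh2-null against WT, Eed-null against WT and Eed-null against Ezh2-null in turn. PRC1 subunits gave 0.14 (0.233), 0.22 (0.134) and 0.09 (0.884), with Bmi1 called in the first and second comparison. The MLL-AF9 programme gave 0.24 (0.335), 0.33 (0.357) and 0.08 (0.906), CDK inhibitors 0.23 (0.179), 0.30 (0.357) and 0.07 (0.818), and imprinted genes 0.12 (0.259), 0.18 (0.147) and 0.06 (0.726). Haematopoietic stem and progenitor genes gave 0.08 (0.432), 0.18 (0.203) and 0.10 (0.682), erythroid genes 0.05 (0.515), 0.07 (0.448) and 0.01 (0.795), and megakaryocyte and platelet genes -0.02 (0.913), 0.25 (0.119) and 0.26 (0.103). B cell genes gave 0.11 (0.363), 0.14 (0.119) and 0.03 (0.655), T and NK cell genes 0.15 (0.117), 0.20 (0.0538) and 0.05 (0.682), and eosinophil, basophil and mast cell genes 0.12 (0.985), 0.32 (0.529) and 0.21 (0.655). Stromal and endothelial genes gave -0.07 (0.259), 0.06 (0.478) and 0.13 (0.0891), p53 target genes 0.11 (0.259), 0.22 (0.102) and 0.12 (0.655), antigen presentation genes 0.01 (0.575), -0.19 (0.817) and -0.19 (0.685), and sex-linked genes -0.09 (0.335), 0.01 (0.896) and 0.10 (0.655).

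Of the lists called in only some comparisons, the others gave -0.11 (0.335) and -0.17 (0.121) for PRC2 subunits in Ezh2-null against WT and Eed-null against Ezh2-null, and in Ezh2-null against WT 0.04 (0.432) for Hox clusters B, C and D, -0.0012 (0.480) for developmental regulators bound by Polycomb, -0.20 (0.335) for monocyte and macrophage genes, -0.08 (0.466) for cell cycle genes and -0.14 (0.334) for Myc and nucleolar genes. In Eed-null against Ezh2-null, granulocyte genes gave -0.05 (0.655) and interferon response genes 0.16 (0.682). Immediate early and stress genes gave 0.29 (0.0746) in Eed-null against WT and 0.12 (0.884) in Eed-null against Ezh2-null.

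Several lists that did not pass with all arrays passed in camera on leaving out 1 array. In Ezh2-null against WT, Myc and nucleolar genes were -0.41 without WT replicate 2 and -0.27 without Ezh2-null replicate 2, but turned to 0.26 without WT replicate 3, and passed each time. Monocyte and macrophage genes were -0.46 without WT replicate 3 and T and NK cell genes 0.20 without Ezh2-null replicate 1. Without WT replicate 2, PRC2 subunits (-0.17), Hox clusters B, C and D (0.10), imprinted genes (0.17) and cell cycle genes (-0.21) passed. In Eed-null against WT, p53 target genes passed without WT replicate 3 (0.30) or Eed-null replicate 1 (0.27), immediate early and stress genes without WT replicate 1 (0.31) or Ezh2-null replicate 3 (0.29), and T and NK cell genes without WT replicate 1 (0.24), Eed-null replicate 1 (0.25) or, at an unchanged 0.20, Ezh2-null replicate 2 or 4. With the granulocyte covariate, chosen after the data were seen, Myc and nucleolar genes (0.36), cell cycle genes (0.16) and monocyte and macrophage genes (-0.47) passed in Ezh2-null against WT, the first and second with the sign changed, and p53 target genes (0.32) in Eed-null against WT. Without both WT replicate 3 and Eed-null replicate 1, Myc and nucleolar genes (0.26) and monocyte and macrophage genes (-0.46) passed in Ezh2-null against WT and p53 target genes (0.36) in Eed-null against WT. The direction of the Myc and nucleolar and cell cycle lists in Ezh2-null against WT is therefore not settled.

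The median, the mean and the direction of the camera test differed in sign for a few lists that did not pass. In Ezh2-null against WT these were Hox clusters B, C and D (median -0.02, mean 0.04, upward), megakaryocyte and platelet genes (median 0.01, mean -0.02, downward) and eosinophil, basophil and mast cell genes (median -0.05, mean 0.12, downward). In Eed-null against WT they were eosinophil, basophil and mast cell genes (median -0.01, mean 0.32, upward) and sex-linked genes (median and mean 0.01, downward), and in Eed-null against Ezh2-null CDK inhibitors (median -0.02, mean 0.07, downward).

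Whole chromosomes were also tested, after the calls were seen. On the chromosome that carries H2-K1, 4 of 852 genes were called in Eed-null against WT (Capn11, Cfb, H2-Q7 and H2-Q8; Fisher's exact test, two-sided, adjusted p = 0.0794), and on the chromosome that carries Ezh2, 2 of 987 were called in Ezh2-null against WT (Gt(ROSA)26Sor and Hebp1; Fisher's exact test, two-sided, adjusted p = 0.0794). On the chromosome that carries Eed, 4 of 1437 genes were called in Eed-null against WT and 20 of 16710 elsewhere (Fisher's exact test, two-sided, adjusted p = 0.293). Against Ezh2-null, 4 were called there and 11 elsewhere (Fisher's exact test, two-sided, adjusted p = 0.0794). No whole chromosome passed, and within 250 measured genes of Ezh2, limma called 0 genes in Ezh2-null against WT. Among arrays of one group the granulocyte score also went against the cell cycle score (r = -0.676, permutation p = 0.0262, -0.827 without WT replicates 1 and 3) and with the monocyte score (r = 0.646, permutation p = 0.0381), and the latter was 0.310 without WT replicates 1 and 3, on which it rests.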
